A study of Homo sapiens with 41 samples.

How the data were processed

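The deposited counts table of the authors was used as it stands, since its values are whole numbers per gene with NCBI Entrez identifiers and symbols. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1, mapped with TopHat2 2.1.0 and Bowtie2 2.2.7 to build GRCh38.p2, and counted with HTSeq 0.9.1. The strand setting, the counted feature type, filters and the gene annotation release were not given in the sources used here. Counts of overlapping and antisense genes, and of near-identical copies, are therefore uncertain. The reads themselves were not used here. The table had 37549 rows, of which 22 were empty in every library, leaving 37527 genes, and all 41 columns matched a sample. An NCBI gene table matched 32924 of them (87.7%) by identifier and gave their chromosomes and biotypes, while coordinates came from GENCODE v29 on GRCh38. No row of the mitochondrial genome was present, so no mitochondrial share could be given.

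Library sizes were scaled with TMM in edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes with too few counts were removed with filterByExpr at a minimum count of 10 within groups. Expansion groups of 585B1-BTAG with d6 were fitted together (21 libraries, 12249 genes, common biological coefficient of variation 0.171, 14 residual degrees of freedom). The trend from c10 to c120 used 18 libraries, 12011 genes, 0.175 and 16, and the aggregates with d6 and c30 used 14 libraries, 13512 genes, 0.204 and 8. Line 1383D6 used 12 libraries, 12218 genes, 0.205 and 6, and the difference between lines used 15 libraries, 12680 genes, 0.182 and 9. Each of 25 comparisons was tested with robust quasi-likelihood F tests. All adjusted p-values for genes in the texts are Benjamini-Hochberg values from edgeR unless DESeq2 is named, and standard errors are the absolute log2 change divided by the square root of F. Levels are CPM of the whole library, and log2 CPM for the principal components used a prior count of 2 and 2000 genes.

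The comparisons, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. Named genes were a panel of 13 germ-cell and pluripotency genes and, in each comparison, the 8 highest and 8 lowest log2 changes among called genes with a mean log2 CPM of at least 4 and groups that did not overlap. Chance gives such separation in 10% of genes for 3 libraries against 3. In place of separation, the trend used a rank correlation of at least 0.8 in size, and differences of changes had no such condition. From each gene list, up to 3 called members with the largest change and the member not called with the highest expression were added. XIST, genes of chromosome Y, pseudogenes and names of the LOC, MIR, SNOR and RNU series were left out. Where a report sentence names a gene only as part of a list result, its level follows the same tables.

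The 24 gene lists covered early germ cell genes, gonadal germ cell and piRNA genes, meiosis, oocyte genes, primed and shared pluripotency, naive pluripotency, primitive streak and mesoderm, DNA methylation machinery, proliferation, p53 targets, immediate early and heat shock genes, and cAMP response. The others covered the amino acid and unfolded protein response, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, cancer-testis genes, imprinted genes, and markers of endoderm, neural and ectoderm cells, mesenchyme, endothelium and blood, gonadal somatic cells, and amnion and surface ectoderm. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with p adjusted over the lists of a comparison, and again with an estimated correlation.

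Replicate numbers were treated as pairs only where there were at least 3 pairs and every pair of libraries with the same number correlated above 0.1 after group means were removed. This held for c120 and c30 against c10, c50 against c30, c70 against c50, c90 against c70 and c120 against c90, for which a fit with the replicate number as a block is reported where it moved a count by more than 1.5-fold. It held for no comparison of 585B1-BTAG expansion cells with d6 (lowest r 0.0553 to 0.0797) and, narrowly, not for the trend (lowest r 0.072). Groups of 2 were not judged, because they give fewer than 3 pairs. Alternatives were RLE scaling, DESeq2 1.42.0 with independent filtering off, no low-count filter beyond 1 count, a minimum count of 30, the replicate block, a fit of only the compared groups, leaving out each library in turn, and for the trend log2 days, no day 10 and no day 120. Runs without genes of chromosomes 9 and 13, without the libraries shifted on them, with crossed replicate blocks in 1383D6, and of lists without sort genes were chosen after seeing the data.

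The procedure was tested on simulated data with known changes of 1.5-fold, 2-fold and 4-fold in 67, 67 and 66 genes. A comparison of c30 with c10 in 1383D6 (n = 2) recovered 6.0%, 32.8% and 83.3% of them with 14 false calls, and the trend 43.3%, 76.1% and 100% with 5. For ag77 against ag35 the shares were 3.0%, 40.3% and 89.4% with 7 false calls, and for c30ag77 against ag77 they were 3.0%, 26.9% and 90.9% with 5. The difference of the c30 to d6 changes between lines recovered 1.5%, 20.9% and 63.6% with 4. The libraries hold 1500346 counts at least, so that 3 counts equal 0.726 to 2.00 CPM.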

Results

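RNA sequencing counts were compared across 41 libraries of human germ-cell precursors made from induced pluripotent stem cells (iPSC) of 2 lines, 585B1-BTAG and 1383D6. Human primordial germ cell-like cells (hPGCLC) are a culture model of primordial germ cells, the embryonic founders of eggs and sperm. They were taken after 6 days of induction (d6), or after 10 to 120 days of expansion culture with forskolin, stem cell factor and basic fibroblast growth factor (c10, c30, c50, c70, c90 and c120). Incipient mesoderm-like cells (iMeLC) are the intermediate between iPSC and hPGCLC. In a xenogeneic reconstituted ovary (xrOvary), hPGCLC are aggregated with mouse fetal ovarian somatic cells; cells sorted after 35 or 77 days are named ag35 and ag77 when they began as d6 cells, and c30ag35 and c30ag77 when they began as c30 cells. Line 585B1-BTAG gave 3 libraries for d6 and for each of the 6 expansion days, and 2 for each of the 4 aggregate groups. Line 1383D6 gave 2 libraries for each of iPSC, iMeLC, d6, c10, c30 and the ITGA6-low cells of c10. Each library was made from amplified cDNA of at most 1 ng of RNA and held 1500346 to 4133993 counts, with a median of 2641975, over 15120 to 19063 genes with at least 1 count.

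Expanded and aggregate cells of 585B1-BTAG were sorted on fluorescent reporters of PRDM1 (BLIMP1) and TFAP2C, and expanded 1383D6 cells on EPCAM and ITGA6 protein, so these genes are selection markers here and not findings. A gene or gene list was called changed at an adjusted p below 0.05. Changes are log2 fold changes ± standard error from edgeR, with p adjusted over all genes of a comparison, and levels are mean counts per 1e6 counts (CPM) ± SD. Where a group held no counts, the fold is a lower limit from a floor of 3 counts over the group, and where it held 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only, because amplified reads are not independent molecules. The p-values measure only the spread between these libraries, which may be technical, since the labels say nothing about separate cultures. Of 175 calls on 24 gene lists fixed beforehand and tested with camera at a preset correlation, 34 held with an estimated correlation, and the p under it is printed wherever a named call was lost. Counts within the list are those with p adjusted over that list alone, and where 2 such counts stand together, higher genes come before lower ones.

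On the 2000 most variable genes, principal component 1 carried 45.8% of the variance, component 2 carried 21.8% and component 3 carried 10.4%. Replicates of a group correlated at r = 0.941 to 0.974 across genes in 31 pairs. Their chi-square per degree of freedom was 2.80 to 11.8, so replicates differed by more than counting error.

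**Figure D1:**
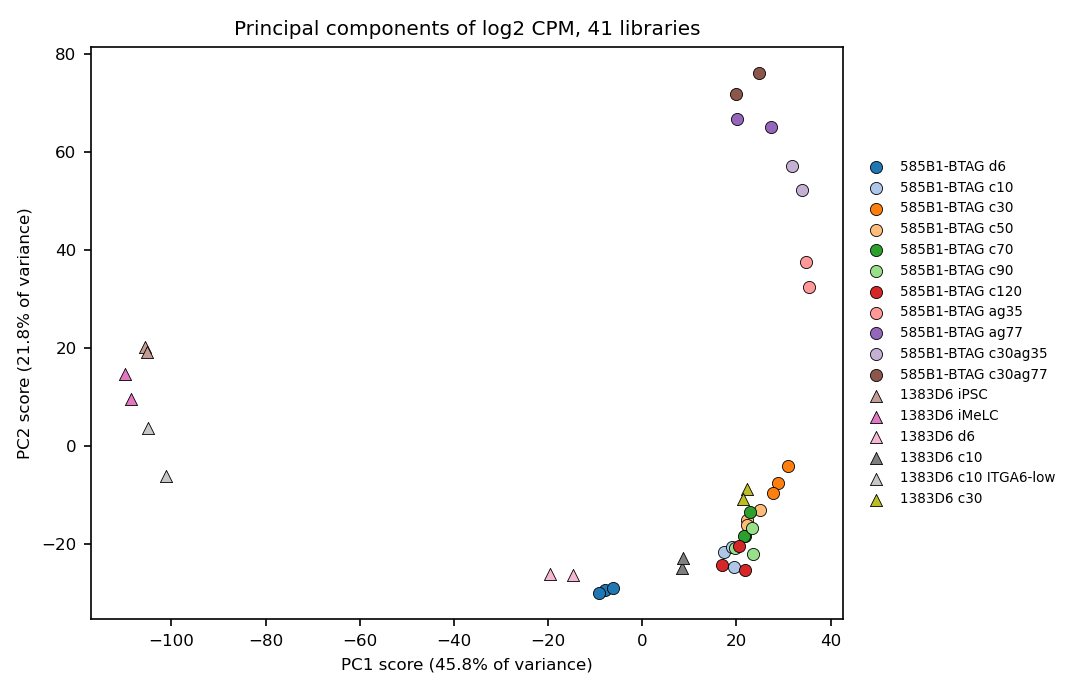
Each point is a library placed on principal components 1 (45.8% of variance) and 2 (21.8%) of log2 CPM, with 41 libraries in 17 groups. The axes are unitless component scores, and libraries of a group lie close together.

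What set iMeLC apart from the iPSC they came from was examined in line 1383D6 (n = 2 per group). LEFTY2, a secreted Nodal inhibitor with counts uncertain because of a close copy, rose by 7.22 ± 0.99 (adjusted p = 0.0118, 1050 ± 628 against 6.92 ± 1.62 CPM), and NODAL itself, the mesendoderm-inducing ligand, rose from 4.55 ± 2.35 to 296 ± 225 CPM (adjusted p = 0.00182). NANOG, a core pluripotency factor, rose by 1.66 ± 0.26 (193 ± 46.9 against 60.3 ± 16.6 CPM), and VIM, the intermediate filament of mesenchymal cells, by 3.43 ± 0.23 (2510 ± 698 against 230.2 ± 5.24 CPM). The LEFTY2 call ended without iPSC replicate 1 (adjusted p = 0.159) or 2 (0.133), and in a fit of these groups alone LEFTY2 (0.0895) and NODAL (0.172) did not pass. SP5, a direct Wnt target, rose at least 85.8-fold (adjusted p = 1.33e-04). The iMeLC libraries differed from each other in primitive streak genes: TBXT (brachyury, listed as T), the streak marker, had 209 counts in one and 18 in the other.

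Other rising genes in iMeLC included the tubulin gene TUBB2A (3.62 ± 0.23, with near-identical copies that make its counts uncertain), NKX1-2 (4.21 ± 0.52) and FST, an activin antagonist (2.95 ± 0.25). Falling genes included HAPLN3 of the matrix (-3.50 ± 0.52) and GPR176 (-3.00 ± 0.34). SOX2, which iPSC express, did not pass (-0.68 ± 0.45, adjusted p = 0.52), nor did SOX17, with no counts in iPSC and 8.8 ± 11.6 CPM in iMeLC (adjusted p = 0.187), though it did in DESeq2 (0.0209) and without iMeLC replicate 2 (1.61e-05). In the p53 target list, 6 of 21 genes rose and none fell, ZMAT3 by 2.83 ± 0.46 among them, with 8 and 0 within the list (camera adjusted p = 2.37e-09; 0.108 with an estimated correlation). The primitive streak and mesoderm list rose with 4 of 24 genes, 10 within the list (camera adjusted p = 5.27e-11; 0.256 with an estimated correlation).

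Between iPSC and iMeLC, 420 of 12218 genes were called, 210 higher and 210 lower, with 390 changed at least 2-fold. The count fell to 148 without iPSC replicate 1, 161 without iPSC replicate 2 and 114 without iMeLC replicate 1, and was 775 when only these groups were fitted and 677 with no low-count filter.

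The step from iMeLC to d6 hPGCLC in 1383D6 was compared next (n = 2 per group). NANOS3 (Entrez 342977), an RNA-binding protein needed for germ-cell survival, rose from no counts to 686 ± 152 CPM, at least 758-fold (adjusted p = 1.56e-09). SOX17, which starts human germ-cell specification, rose by 5.91 ± 0.69 (497 ± 71.4 against 8.8 ± 11.6 CPM), TFAP2C by 5.07 ± 0.33 (186 ± 66.7 against 5.64 ± 1.73 CPM) and NANOG by 1.79 ± 0.25 (643 ± 9.14 against 193 ± 46.9 CPM). SOX2 fell at least 218-fold to no counts (adjusted p = 9.95e-05), and the methyltransferase gene DNMT3B fell by -4.37 ± 0.38 (39.5 ± 4.47 against 848 ± 209.6 CPM). The chemokine receptor CXCR4, used by migrating germ cells, rose by 7.12 ± 0.35 (adjusted p = 6.23e-12), and TCL1A, an AKT coactivator, by 7.87 ± 0.45 (adjusted p = 5.93e-10).

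KLF4, a naive pluripotency factor, rose by 5.42 ± 0.38 at d6 (299 ± 26.2 against 7.07 ± 3.75 CPM), and SUSD2, a naive surface marker, with a count ratio of 74.5, 20.3 to 619.9. CRHBP rose at least 2057-fold and LCP1 had a count ratio of 612, 169 to 5055 against 1 to 3 iMeLC counts. LEFTY2 (-8.42 ± 1.09), LEFTY1 (-8.08 ± 0.79), the heparan sulfate proteoglycan GPC4 (-8.15 ± 0.43), BCAT1 (-8.07 ± 0.44), FST (-6.77 ± 0.34) and the Wnt receptor FZD7 (-6.58 ± 0.64) fell. The epiblast factor OTX2 fell at least 44.6-fold. TBXT did not pass (1.16 ± 0.95, adjusted p = 0.405) except without iMeLC replicate 1 (2.41e-04). The amnion-related factor GATA2 rose at least 60.8-fold.

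Of 21 early germ cell genes, 17 rose and 3 fell at d6, 17 and 3 within the list (camera adjusted p = 1.85e-20, and 0.00143 with an estimated correlation). Without the 4 genes used in sorting, 14 of 17 rose and 3 fell (3.19e-17, and 0.0173). Primed and shared pluripotency genes fell, 15 of 23 against 4 that rose, 4 and 17 within the list (camera adjusted p = 7.51e-10, and 0.016 with an estimated correlation). Naive pluripotency genes rose in 5 of 8 cases, 5 within the list (camera adjusted p = 4.71e-06, and 0.016 with an estimated correlation). Proliferation genes fell in 16 and rose in 2 of 32 cases, 2 and 17 within the list, with AURKA (-1.70 ± 0.26) and MCM4 (-1.38 ± 0.24) lower (camera adjusted p = 0.00303; 0.158 with an estimated correlation). In total 4187 of 12218 genes were called, 2289 higher and 1898 lower, with 3352 changed at least 2-fold.

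Whether expanded cells kept the expression of d6 hPGCLC was asked in 585B1-BTAG by comparing c10, c30 and c120 with d6 (n = 3 per group). At c30, DPPA3 (STELLA; Entrez 359787, GRCh38 chromosome 12, 7711454 to 7717559), a maternal-effect gene of germ cells, rose by 5.70 ± 0.56 (adjusted p = 1.12e-06, 206 ± 7.56 against 4.26 ± 2.89 CPM). KIT (Entrez 3815, chromosome 4, 54657918 to 54740715), the receptor of the stem cell factor in the medium, rose by 1.38 ± 0.24 (208 ± 22.1 against 80.1 ± 12.6 CPM). POU5F1, a core pluripotency factor, fell by -0.98 ± 0.14 (1155 ± 151 against 2272 ± 559 CPM) and SOX17 by -1.16 ± 0.15 (142 ± 18.9 against 316 ± 12.4 CPM). NANOS3 (0.16 ± 0.29, adjusted p = 0.718) and NANOG (-0.31 ± 0.13, adjusted p = 0.0603) did not pass, NANOG except without d6 replicate 2 (0.0409). ID3, an inhibitor of DNA binding, fell by -7.29 ± 0.29 (5.56 ± 1.4 against 886 ± 112 CPM), ID2 by -6.14 ± 0.47, ID1 by -4.81 ± 0.21 and MSX2 by -4.64 ± 0.31.

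SMARCA2, the BRM chromatin remodeller (Entrez 6595), rose by 4.74 ± 0.19 at c30 (287 ± 14.9 against 10.6 ± 3.57 CPM), and the oocyte complex member KHDC3L from 1 count at d6 to 421 ± 55.5 CPM (count ratio 3142, 564 to 124100). FAM9C (5.70 ± 0.26), the endothelial adhesion gene ESAM (3.81 ± 0.25), the transporter ABCG2 (3.72 ± 0.24) and CDCA7L (3.49 ± 0.22) were also among the largest rises. NKX1-2 (-5.08 ± 0.34), the protease TMPRSS11E (-4.97 ± 0.32), the iron regulator ACO1 (-4.43 ± 0.25) and BTG2 (-3.94 ± 0.31) were among the largest falls. GTSF1, a piRNA-pathway cofactor, rose at least 29.7-fold from no counts (adjusted p = 6.33e-07, 11.6 ± 3.41 CPM at c30). The germ-plasm factor DND1 rose by 2.93 ± 0.31 and the meiotic chromosome-axis gene HORMAD1 by 2.99 ± 0.26 (82.3 ± 13.8 against 10.3 ± 4.92 CPM). SOX2 had no counts in either group, DAZL had none, and DDX4 had 3 counts at c30.

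Of 9 gonadal germ cell and piRNA genes, 6 rose at c30, 8 and 0 within the list (camera adjusted p = 3.49e-06, and 0.00415 with an estimated correlation). The oocyte list rose with 5 of 9, 7 within the list (camera adjusted p = 0.00106, and 0.0294 with an estimated correlation), led by KHDC3L and NLRP7, the latter uncertain because of NLRP2. Of 10 naive pluripotency genes, 5 rose and 2 fell, 5 and 2 within the list (camera adjusted p = 0.00185, and 0.0221 with an estimated correlation), DPPA5 at least 18.4-fold. Early germ cell genes split, 7 higher and 7 lower of 21, 7 and 7 within the list (camera adjusted p = 0.47). Meiosis genes rose in 4 of 13 cases, 4 within the list, HORMAD1 among them (camera adjusted p = 0.0394; 0.0761 with an estimated correlation). All 3 tested of 34 cancer-testis genes rose, 3 within the list, PRAME at least 11-fold. Genes silent at d6 were tested only if higher elsewhere, which favours rises.

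Glycolysis and hypoxia genes fell at c30 in 15 and rose in 1 of 26 cases, 1 and 16 within the list (camera adjusted p = 2.8e-07, and 0.0047 with an estimated correlation). Among them, the hypoxia-induced NDRG1 fell by -3.89 ± 0.32 (6.24 ± 3.59 against 93.4 ± 9.86 CPM) and the glucose transporter SLC2A3 by -3.03 ± 0.20 (54.6 ± 10.1 against 442 ± 43.8 CPM), while ENO1 did not pass (-0.52 ± 0.23), except in DESeq2 (adjusted p = 0.0447) and without d6 replicate 3 (0.0206) or c30 replicate 2 (0.022). Imprinted genes fell in 8 and rose in 1 of 21 cases, 1 and 9 within the list (camera adjusted p = 0.00185, and 0.0141 with an estimated correlation), with SGCE (-3.63 ± 0.30) and PEG10 (-3.81 ± 0.49) lowest and MEST not passing (-0.30 ± 0.12) except in DESeq2 (adjusted p = 0.0442). Cholesterol synthesis genes fell in 11 and rose in 1 of 23, 1 and 15 within the list, such as HMGCS1 (-1.76 ± 0.26; camera adjusted p = 0.00185; 0.115 with an estimated correlation). Amino acid and unfolded protein response genes fell in 9 and rose in 1 of 21, 1 and 9 within the list, SLC7A5 among them (-2.35 ± 0.33; camera adjusted p = 0.00808; 0.078 with an estimated correlation). Immediate early and heat shock genes fell in 9 and rose in 1 of 15, 1 and 11 within the list, FOS by -2.99 ± 0.49 (camera adjusted p = 0.00185; 0.0507 with an estimated correlation).

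Primitive streak and mesoderm genes fell at c30 in 7 and rose in 1 of 16 cases, 1 and 7 within the list, HAND1 with a count ratio of 0.0141, 0.00169 to 0.052 (camera adjusted p = 0.00106; 0.056 with an estimated correlation), whereas TBXT did not pass (0.20 ± 0.13, 175 ± 2.92 against 151 ± 11.3 CPM). Amnion and surface ectoderm genes fell in 8 of 12 cases and rose in 3, 3 and 8 within the list (camera adjusted p = 0.00461; 0.127 with an estimated correlation). The p53 list fell, 6 lower and 1 higher of 20, 1 and 6 within the list (camera adjusted p = 0.023; 0.056 with an estimated correlation). The cAMP response list, of interest because forskolin raises cAMP, fell with 5 of 13 genes against 3 that rose, 3 higher and 6 lower within the list, PDE4B by -3.11 ± 0.49 (camera adjusted p = 0.0372; 0.134 with an estimated correlation). Lists without a call at c30 were primed and shared pluripotency (5 higher and 6 lower of 18), DNA methylation machinery (1 and 1 of 23), proliferation (8 and 3 of 32), oxidative phosphorylation (4 and 2 of 33) and mesenchyme (4 and 8 of 20). Endoderm (2 and 1 of 6), neural and ectoderm (2 and 2 of 6), endothelial and blood (4 and 3 of 7) and gonadal somatic lists (1 and 0 of 5) had no call either. Adjusted over the list alone, the higher and lower counts became 5 and 7 for primed pluripotency, 9 and 3 for proliferation, 4 and 1 for oxidative phosphorylation and 2 and 3 for the neural list.

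Median and mean changes at c30 differed in sign for the primed pluripotency list (-0.13 and 0.27, the test pointing down), the neural list (-0.28 and 0.63) and the endothelial list (1.67 and -0.46). Single genes of these lists moved far: the endoderm factor FOXA2 rose by 4.90 ± 0.49, the endothelial cadherin CDH5 by 3.27 ± 0.29 and the left-right gene LEFTY1 by 2.98 ± 0.28, while GATA2 fell by -6.17 ± 0.58 and LIN28B by -3.33 ± 0.38. The collagen gene COL3A1 fell (count ratio 0.00607, 0.00125 to 0.0179), from d6 libraries that varied widely (68.8 ± 50.8 CPM), and VIM did not pass (-0.09 ± 0.11). At c30, 3919 of 12249 genes were called, 1913 higher and 2006 lower, with 2121 changed at least 2-fold. Tested on simulated data, this comparison recovered 20.9% of 1.5-fold, 64.2% of 2-fold and 98.5% of 4-fold changes with 4 false calls.

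Many of these changes were called by c10 (n = 3 per group). DPPA3 rose by 5.62 ± 0.56 (194 ± 27.4 against 4.26 ± 2.89 CPM), SMARCA2 by 4.45 ± 0.19 and KHDC3L with a count ratio of 2184, 392 to 86320, while ID3 fell by -5.62 ± 0.25 (18.1 ± 5.12 against 886 ± 112 CPM) and MSX2 by -5.61 ± 0.34. POU5F1 (-0.93 ± 0.14) and SOX17 (-1.05 ± 0.15) fell, KIT rose (0.87 ± 0.24), and NANOG (-0.28 ± 0.13, adjusted p = 0.103) and NANOS3 (0.20 ± 0.29, adjusted p = 0.674) did not pass. TCL1B rose from 82 ± 7.82 to 377 ± 50.2 CPM, and its neighbour TCL1A did not pass (0.27 ± 0.44). The KIT call ended without d6 replicate 3 (adjusted p = 0.0553) or c10 replicate 1 (0.0543). HORMAD1 rose by 2.84 ± 0.26 and LEFTY1 by 3.29 ± 0.28.

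Naive pluripotency genes rose at c10 (5 higher and 2 lower of 10, 6 and 2 within the list, camera adjusted p = 0.00109 and 0.0291 with an estimated correlation). Imprinted genes fell (10 lower and 2 higher of 21, 3 and 10 within the list, camera adjusted p = 0.00641 and 0.0353 with an estimated correlation), SGCE by -3.87 ± 0.30. Glycolysis and hypoxia genes fell in 11 and rose in 1 of 26 cases (camera adjusted p = 0.00605; 0.0954 with an estimated correlation), NDRG1 by -3.15 ± 0.30. In all, 3224 of 12249 genes were called at c10, 1555 higher and 1669 lower, with 1657 changed at least 2-fold.

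The difference from d6 was measured again after 120 days (n = 3 per group). SMARCA2 (4.83 ± 0.19, 304 ± 35 against 10.6 ± 3.57 CPM), FAM9C (5.86 ± 0.26), DPPA3 (4.88 ± 0.57), KIT (1.28 ± 0.24) and CDH5 (3.95 ± 0.28) rose, and ID3 (-4.32 ± 0.23), MSX2 (-4.37 ± 0.30), PEG10 (-4.44 ± 0.52) and NKX1-2 (-4.52 ± 0.32) fell. TCL1A fell by -5.88 ± 0.62 (8.8 ± 8.68 against 523 ± 91.1 CPM), although it had not passed at c10 or c30. NANOG was lower by -0.52 ± 0.13 (adjusted p = 0.00198), as were POU5F1 (-1.09 ± 0.14) and SOX17 (-0.99 ± 0.15), and the NANOG call ended without the shifted libraries named below (adjusted p = 0.362). The glycolysis and hypoxia list fell, 15 lower and 1 higher of 26, 1 and 17 within the list (camera adjusted p = 1.94e-07, and 0.00971 with an estimated correlation). Gonadal germ cell genes rose in 5 of 9 cases, 5 and 1 within the list (camera adjusted p = 0.00735; 0.0521 with an estimated correlation). In total 3383 genes were called, 1679 higher and 1704 lower, 1857 of them at least 2-fold. Genes of chromosome 13 in c120 replicate 2 and of chromosome 9 in c120 replicate 3 were shifted upward as a block, and without the shifted libraries, which also leaves fewer libraries, 1900 genes were called.

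**Figure D2:**
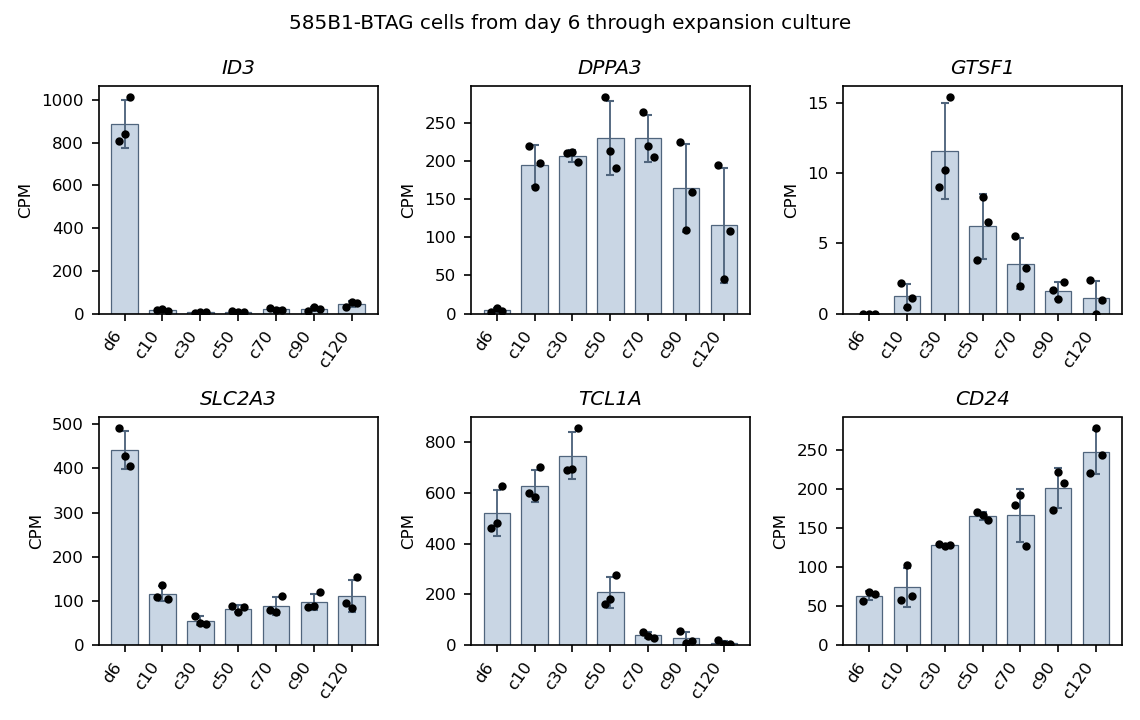
Bars show mean CPM of ID3, DPPA3, GTSF1, SLC2A3, TCL1A and CD24 in d6 and c10 to c120 cells of 585B1-BTAG, with SD as error bars and each library as a point (n = 3). ID3 fell from 886 ± 112 CPM at d6 to 44.3 ± 12.4 at c120, and TCL1A from 523 ± 91.1 to 8.8 ± 8.68.

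How stable the cells were during expansion was followed between successive days, in pairs of 3 libraries. From c10 to c30, the growth factor gene PTN rose by 2.46 ± 0.47 (55.4 ± 8.78 against 9.95 ± 0.64 CPM), the endogenous retroviral envelope gene ERVW-1 (syncytin 1) by 1.41 ± 0.20 and GTSF1 by 3.09 ± 0.59. S100A14 (-2.01 ± 0.22), LEFTY2 (-1.76 ± 0.31), the neuropeptide gene GAL (-1.68 ± 0.27), ACO1 (-1.58 ± 0.25) and TDGF1, the Nodal coreceptor (-1.20 ± 0.18), fell. No gene of the germ-cell and pluripotency panel was called, but the replicate block called KIT (0.51 ± 0.23, adjusted p = 0.00112), DNMT3B (-0.63 ± 0.22, 0.0283) and the sort markers PRDM1 (0.00514) and TFAP2C (0.0357). PRDM1 also passed in DESeq2 (0.0468) and without c10 replicate 1 (0.0252) or c30 replicate 3 (0.012). The gonadal germ cell list rose, 3 of 9 with 6 within the list (camera adjusted p = 9.59e-09, and 7.17e-04 with an estimated correlation), DND1 by 1.24 ± 0.27 and PNLDC1, a piRNA trimmer, by 2.01 ± 0.35, though DND1 did not pass without c30 replicate 3 (adjusted p = 0.0714). Of 26 glycolysis and hypoxia genes, 7 fell, with 1 and 9 within the list (camera adjusted p = 3.85e-07, and 0.00552 with an estimated correlation), SLC2A3 by -1.10 ± 0.20. Cholesterol synthesis genes fell as a list (2 of 23, 5 within the list, camera adjusted p = 1.92e-06 and 0.0368 with an estimated correlation), as did amino acid response genes (3 of 21, 6 within the list, camera adjusted p = 9.56e-05 and 0.0255 with an estimated correlation).

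Between c10 and c30, 432 of 12249 genes were called, 195 higher and 237 lower, with 211 changed at least 2-fold. Replicates with the same number resembled each other across these days, and with the replicate number as a block the count was 1013. It fell to 256, 214 and 274 without c10 replicates 1, 2 and 3, and to 242, 264 and 259 without c30 replicates 1, 2 and 3.

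Later steps gave few calls (n = 3 per group). From c30 to c50, only COTL1, an actin-binding protein, was called (1.08 ± 0.20, adjusted p = 0.0451, 59.1 ± 14.2 against 28 ± 6.43 CPM), against 523 genes at an unadjusted p below 0.05 and 3 called by DESeq2, and it did not pass in a fit of these groups alone (0.0966). The count was 11 with the replicate block, 12 with no low-count filter, and 0 without c30 replicate 1 or 3 or c50 replicate 1 or 2. The amnion and surface ectoderm list rose with no single gene called and 3 within the list (camera adjusted p = 3.56e-06; 0.104 with an estimated correlation). From c50 to c70 no gene passed, with 285 at an unadjusted p below 0.05, 0 by DESeq2, and 1 for these groups alone or with no filter. From c70 to c90 none passed, with 433 at that unadjusted p and 0 by DESeq2, and the replicate block or no filter gave 1. With that block, but not without it, the proliferation list fell and the amnion list rose (camera adjusted p = 0.034 each, against 0.0698 and 0.2, and 0.457 and 0.573 with an estimated correlation). From c90 to c120 none passed, with 427 at that unadjusted p and 0 by DESeq2. No filter, or leaving out c120 replicate 1, gave 2. Each unadjusted count is lower than chance gives in 12249 genes.

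With camera the mesenchyme, amnion and naive lists rose from c90 to c120 and the meiosis list fell (adjusted p = 0.02, 0.02, 0.03 and 0.02; 0.432, 0.437, 0.147 and 0.102 with an estimated correlation). A simulated c70 to c50 comparison recovered 14.9% of 1.5-fold, 65.7% of 2-fold and 97.0% of 4-fold changes with 9 false calls, so smaller changes would mostly be missed.

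Over the whole of expansion, c120 was compared with c10 (n = 3 per group). TCL1A fell by -6.15 ± 0.62 (8.8 ± 8.68 against 628 ± 63.9 CPM), and the surface glycoprotein gene CD24 rose by 1.75 ± 0.17 (247 ± 28.5 against 74.2 ± 24.9 CPM). SOX11, a neural and progenitor factor, rose by 1.76 ± 0.26, the matrix gene POSTN by 5.11 ± 0.65 (43.4 ± 24.5 against 1.22 ± 0.541 CPM) and the smooth muscle gene TAGLN by 1.67 ± 0.27. LEFTY2 fell by -1.97 ± 0.32, S100A14 by -1.60 ± 0.21 and lactate dehydrogenase LDHA by -0.68 ± 0.13 (585 ± 36 against 938 ± 10.7 CPM). DPPA3 (-0.74 ± 0.38, adjusted p = 0.338), POU5F1 (-0.16 ± 0.14, adjusted p = 0.619) and NANOG (-0.24 ± 0.13, adjusted p = 0.329) did not pass, but DPPA3 did without c120 replicate 1 (0.0257). With the replicate block KIT (0.42 ± 0.23, adjusted p = 0.0135) and the sort markers PRDM1 (0.0216) and TFAP2C (0.00486) passed.

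Between c10 and c120, SAMD3 (2.08 ± 0.30), PDZRN3 (2.13 ± 0.36) and CEACAM6 (2.40 ± 0.30, uncertain because of near-identical relatives) rose, and PROCR (-1.61 ± 0.31) and UCP2 (-1.55 ± 0.25) fell. Without the shifted libraries, SOX11 (adjusted p = 0.0942), SAMD3 (0.147), PDZRN3 (0.163), PROCR (0.521), UCP2 (0.228), TAGLN (0.406), LEFTY2 (0.227), LDHA (0.263) and HK2 (0.515) did not pass. Primed and shared pluripotency genes fell in 3 of 18 cases, 5 within the list (camera adjusted p = 1.14e-04, and 0.049 with an estimated correlation). Glycolysis and hypoxia genes fell in 3 of 26 cases, 6 within the list (camera adjusted p = 3.95e-05, and 0.0477 with an estimated correlation), HK2 by -1.37 ± 0.26. Mesenchyme genes rose in 4 and fell in 1 of 20 cases, 8 and 1 within the list (camera adjusted p = 3.95e-05; 0.0524 with an estimated correlation), and amnion genes in 4 of 12, 7 and 1 within the list (camera adjusted p = 2.05e-04; 0.109 with an estimated correlation).

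Between c10 and c120, 485 of 12249 genes were called, 279 higher and 206 lower, 279 of them at least 2-fold. Among chromosome 13 genes, 15 of 235 (6.38%) were called higher, and among chromosome 9 genes 20 of 489 (4.09%), against 227 of 10945 (2.07%) on the other autosomes. Without genes of chromosomes 9 and 13 the count was 440. Without the shifted libraries, c90 replicate 2 and c120 replicates 2 and 3, it was 28, a fit with 1 library left at c120. Leaving out c10 replicates 1, 2 and 3 gave 278, 323 and 217, and leaving out c120 replicates 2 and 3 gave 259 and 226. The replicate block gave 1131, and a fit of these groups alone 291.

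A linear trend per 30 days was also fitted over the 18 libraries from c10 to c120. TCL1A fell by -1.99 ± 0.20 per 30 days (rank correlation with day -0.912), while SOX11 rose by 0.54 ± 0.06 (rank correlation 0.931), CD24 by 0.41 ± 0.05 (rank correlation 0.925) and SAMD3 by 0.61 ± 0.07. The naive pluripotency factor ZFP42 (REX1) fell by -0.39 ± 0.09 and the cardiac actin gene ACTC1 by -0.36 ± 0.04. POSTN (1.03 ± 0.17) and TAGLN (0.40 ± 0.07) rose, but without the shifted libraries POSTN (adjusted p = 0.226) and TAGLN (0.109) did not pass, nor did ZFP42 without day 10 (0.0915) or POSTN without day 120 (0.183). No panel gene had a called trend, but NANOG (-0.08 ± 0.03, adjusted p = 0.131) passed with the replicate block (0.045) and without c120 replicate 1 (0.0242). Mesenchyme genes rose in 5 and fell in 1 of 19 cases, 10 and 1 within the list (camera adjusted p = 6.38e-06, and 0.0237 with an estimated correlation). Amnion and surface ectoderm genes rose in 4 of 10, 6 within the list (camera adjusted p = 4.2e-06, and 0.0394 with an estimated correlation), and neural and ectoderm genes in 1 of 6, 3 within the list (camera adjusted p = 0.015, and 0.0448 with an estimated correlation).

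Primed and shared pluripotency genes fell along the trend in 2 of 18 cases, 5 within the list (camera adjusted p = 8.12e-04, and 0.0394 with an estimated correlation). In all, 422 of 12011 genes had a called trend, 254 rising and 168 falling. Chromosome 13 gave 15 of 230 rising genes (6.52%) and chromosome 9 gave 22 of 481 (4.57%), against 204 of 10738 (1.9%) on the other autosomes. The count was 384 without those chromosomes, 50 without the shifted libraries, 96 without day 120, 274 without c120 replicate 2 and 189 without c120 replicate 3.

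**Figure D3:**
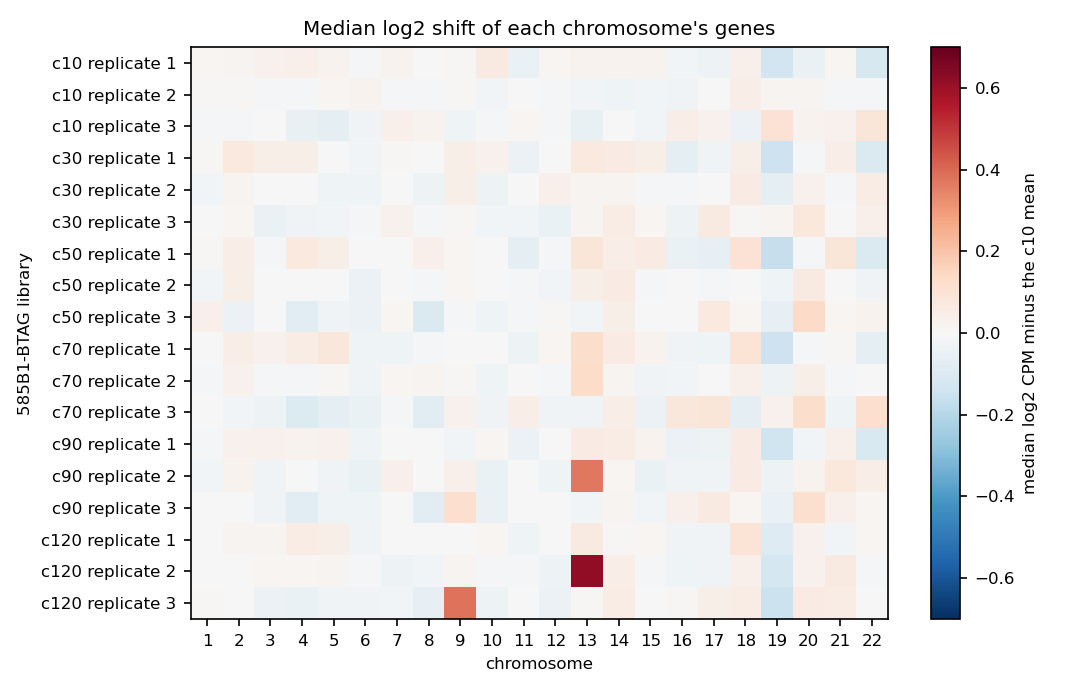
The heat map shows the median log2 difference of each autosome's genes from the c10 mean, for 18 libraries by 22 autosomes. Chromosome 13 stood 0.37 higher in c90 replicate 2 and 0.622 in c120 replicate 2, and chromosome 9 stood 0.381 higher in c120 replicate 3, against -0.161 to 0.135 elsewhere.

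Whether hPGCLC move towards gonadal germ cells in xrOvary was followed from d6 cells of 585B1-BTAG (d6 n = 3, ag35 and ag77 n = 2). After 35 days, GTSF1 rose at least 75.1-fold from no counts (adjusted p = 3.89e-08), the meiotic axis gene HORMAD1 by 3.61 ± 0.31 (126 ± 30.9 against 10.3 ± 4.92 CPM) and DND1 by 4.22 ± 0.34 (115 ± 43.7 against 5.8 ± 3.22 CPM). KIT rose by 2.32 ± 0.17 (399.7 ± 13.8 against 80.1 ± 12.6 CPM), DPPA3 by 3.98 ± 0.41 (62.6 ± 15.4 against 4.26 ± 2.89 CPM) and PRAME, a cancer-testis gene, at least 21.5-fold. ID2 (-8.84 ± 0.93), ID3 (-8.57 ± 1.34) and fibronectin FN1 (-6.97 ± 0.59) fell, as did the mitotic ubiquitin-conjugating enzyme gene UBE2C (-1.99 ± 0.23, 64.2 ± 4.41 against 256 ± 5.34 CPM). SOX17 (-1.08 ± 0.17), NANOG (-0.75 ± 0.19) and POU5F1 (-0.76 ± 0.19) fell, though NANOG did not pass without ag35 replicate 2 (adjusted p = 0.0804) and POU5F1 not without ag35 replicate 1 (0.0707). DAZL and DDX4, markers of gonadal germ cells, had 4 counts each and did not pass (adjusted p = 0.712 and 0.487).

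SMARCA2 (299 ± 84.8 CPM at ag35), the Polycomb gene BMI1 (3.32 ± 0.22) and CEBPA (3.28 ± 0.28) rose at ag35. HMGA2 (-6.72 ± 0.45), NKX1-2 (-6.12 ± 0.43), SERPINE2 (-6.06 ± 0.29) and GJA1 (-5.95 ± 0.42) fell. Gonadal germ cell and piRNA genes rose in 11 of 21 cases, 12 within the list (camera adjusted p = 2.82e-06; 0.0952 with an estimated correlation), RNF17 at least 13.8-fold and PLD6 at least 10.9-fold. Meiosis genes rose in 8 and fell in 1 of 22 cases, 9 and 1 within the list (camera adjusted p = 0.00353; 0.085 with an estimated correlation), HFM1 by 4.46 ± 0.65. Proliferation genes fell in 20 of 32, 22 within the list, PLK1 by -2.66 ± 0.32 (camera adjusted p = 1e-06; 0.133 with an estimated correlation), although PCNA did not pass (-0.34 ± 0.20). Naive genes rose in 6 and fell in 1 of 10, 6 and 1 within the list (camera adjusted p = 9.58e-04, and 0.0466 with an estimated correlation), ALPPL2 by 4.77 ± 0.41.

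At ag35, 19 of 26 glycolysis and hypoxia genes fell, 20 within the list (camera adjusted p = 8.28e-10, and 0.00782 with an estimated correlation), SLC2A3 by -4.58 ± 0.34 (18.4 ± 8.45 against 442 ± 43.8 CPM) and SLC2A1 by -3.01 ± 0.21. Amino acid and unfolded protein response genes fell in 15 of 21, 16 within the list (camera adjusted p = 2.83e-06, and 0.00782 with an estimated correlation). Mesenchyme genes fell in 13 and rose in 1 of 22, 1 and 14 within the list (camera adjusted p = 1.5e-06; 0.0657 with an estimated correlation), and endoderm genes rose in 7 and fell in 1 of 10, 8 and 1 within the list, FOXA2 by 5.31 ± 0.59 and HHEX by 4.07 ± 0.35 (camera adjusted p = 0.00281; 0.0657 with an estimated correlation). UHRF1, which recruits the maintenance methyltransferase, fell by -2.61 ± 0.47, and the imprinted noncoding RNA MEG3 rose at least 93-fold. In total 5256 of 13512 genes were called, 2642 higher and 2614 lower, with 3733 changed at least 2-fold.

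From ag35 to ag77 (n = 2 per group), PRAME rose by 5.62 ± 0.39 (429 ± 178 against 8.69 ± 3.33 CPM), and MAEL, a piRNA factor, at least 69.4-fold (adjusted p = 6.65e-04). PIWIL2, a piRNA-binding protein, rose by 2.53 ± 0.45 (55 ± 30.5 against 9.52 ± 5.2 CPM) and DDX4 (VASA; Entrez 54514, chromosome 5, 55738017 to 55817157) by 5.95 ± 1.40 (adjusted p = 0.0456, 34 ± 39.3 against 0.526 ± 0.399 CPM). DDX4 did not pass without ag35 replicate 1 (adjusted p = 0.325), ag35 replicate 2 (0.227) or ag77 replicate 2 (0.0693), with no low-count filter (0.0605) or in a fit of these groups alone (0.0519). DAZL averaged 177 ± 95.9 against 0.539 ± 0.762 CPM but its libraries differed, and it did not pass (8.32 ± 1.86, adjusted p = 0.106), although it did in DESeq2 (0.0195) and in a fit of these groups alone (9.07e-05). CXCR4 fell by -3.10 ± 0.26 (18.3 ± 7.7 against 155 ± 3.55 CPM), the glutathione peroxidase GPX2 by -2.96 ± 0.28 and FAM20A by -3.12 ± 0.35. KIT (-0.02 ± 0.18) and DPPA3 (1.04 ± 0.33, adjusted p = 0.0826) did not pass, although DPPA3 did in DESeq2 (0.0243), with no low-count filter (2.23e-04) and without ag77 replicate 2 (0.00335).

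WDR66 (2.76 ± 0.45) and SKAP2 (2.75 ± 0.44) rose from ag35 to ag77, with NLRP2 (3.16 ± 0.30) and NLRP7 (2.40 ± 0.33) uncertain because each may share reads with the other. PIEZO2 (-3.02 ± 0.52), ANGPTL4 (-2.65 ± 0.39) and FOXA2 (-4.39 ± 0.59) fell. Cancer-testis genes rose in 7 of 11 cases, 9 within the list (camera adjusted p = 1.83e-16, and 0.0496 with an estimated correlation). Proliferation genes rose in 11 of 32, 23 within the list (camera adjusted p = 1.8e-15; 0.099 with an estimated correlation). Gonadal germ cell and piRNA genes rose in 7 of 21, 14 within the list (camera adjusted p = 7.25e-10; 0.099 with an estimated correlation), and meiosis genes in 2 of 22, 4 within the list, SPATA22 by 1.79 ± 0.33 (camera adjusted p = 0.0139; 0.188 with an estimated correlation). Mesenchyme genes rose in 6 and fell in 1 of 22 cases, 11 and 1 within the list, COL1A1 with a count ratio of 159, 43.8 to 1322 (camera adjusted p = 6.84e-06; 0.099 with an estimated correlation).

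In this step 687 of 13512 genes were called, 249 higher and 438 lower, with 589 changed at least 2-fold. The count was 263 without ag35 replicate 1, 349 without ag35 replicate 2 and 211 without ag77 replicate 2. It was 414 in a fit of these groups alone.

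The same course was followed for c30 cells placed in xrOvary (c30 n = 3, aggregates n = 2). From c30 to c30ag35, GTSF1 rose by 3.11 ± 0.31 (102 ± 51 against 11.6 ± 3.41 CPM), PIWIL2 by 3.27 ± 0.48 (30.3 ± 13 against 3.08 ± 0.613 CPM), PRAME by 3.63 ± 0.38 (54.7 ± 20.1 against 4.24 ± 1.78 CPM) and KIT by 0.84 ± 0.17 (377 ± 47.3 against 208 ± 22.1 CPM). TDGF1 fell at least 129.9-fold to no counts, CXCR4 by -2.39 ± 0.23 and the glucose transporter SLC2A1 by -1.97 ± 0.20. DPPA3 (0.12 ± 0.29), POU5F1 (0.40 ± 0.18) and DAZL (12.4 ± 16.8 against 0 CPM, adjusted p = 0.199) did not pass, but DAZL did in DESeq2 (0.0197) and without c30ag35 replicate 1 (0.00102). POU5F1 passed in a fit of these groups alone (0.0492).

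NLRP7 (3.54 ± 0.32) and UGT3A2 (2.54 ± 0.38) rose at c30ag35. HAPLN1 (-6.29 ± 0.57), FAM20A (-4.74 ± 0.35), EMB (-4.18 ± 0.25) and KRT19 (-4.18 ± 0.53) fell. Gonadal germ cell and piRNA genes rose in 7 of 21 cases, 8 and 1 within the list (camera adjusted p = 8.39e-05; 0.201 with an estimated correlation). Amino acid and unfolded protein response genes fell in 10 of 21, 10 within the list (camera adjusted p = 8.1e-05, and 0.0275 with an estimated correlation), PSAT1 by -2.46 ± 0.25. Mesenchyme genes fell in 9 of 22, 2 and 10 within the list (camera adjusted p = 5.92e-05; 0.138 with an estimated correlation), FN1 by -3.78 ± 0.61. In all, 2332 of 13512 genes were called, 1000 higher and 1332 lower, with 1580 changed at least 2-fold, and 1153 without c30ag35 replicate 2.

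From c30ag35 to c30ag77 (n = 2 per group), PRAME rose by 3.05 ± 0.33 (451 ± 59.2 against 54.7 ± 20.1 CPM), MAEL with a count ratio of 74.1, 25 to 362, and PIWIL1, a piRNA-binding protein, by 3.96 ± 0.63 (40.9 ± 5.84 against 2.65 ± 2.25 CPM). ELAVL2, a germline and neural RNA-binding protein, rose by 2.79 ± 0.43, and MAEL did not pass in DESeq2 (adjusted p = 0.101). DDX4 (48.9 ± 31.9 against 2.5 ± 1.66 CPM, adjusted p = 0.0717) and DAZL (239 ± 36.4 against 12.4 ± 16.8 CPM, adjusted p = 0.177) did not pass. GPX2 (-2.56 ± 0.28), CXCR4 (-1.84 ± 0.27), SPARC (-2.31 ± 0.38), LCP1 (-2.22 ± 0.27) and POU5F1 (-0.83 ± 0.20) fell, POU5F1 not passing without c30ag35 replicate 1 (adjusted p = 0.0518) or 2 (0.103) or c30ag77 replicate 2 (0.186). DAZL passed without c30ag35 replicate 1 (adjusted p = 0.0193) or 2 (0.00222). DDX4 passed in a fit of these groups alone (0.00358) and with the replicate block (1.06e-05).

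TP53INP1 (2.31 ± 0.34) rose from c30ag35 to c30ag77, and GSTA2 (-4.75 ± 0.61, uncertain because of near-identical copies) fell. Cancer-testis genes rose in 3 of 11 cases, 7 within the list (camera adjusted p = 1.85e-08; 0.189 with an estimated correlation). Gonadal germ cell and piRNA genes rose in 6 and fell in 1 of 21, 11 and 1 within the list (camera adjusted p = 4.27e-07; 0.217 with an estimated correlation). In all, 557 genes were called, 198 higher and 359 lower, with 420 changed at least 2-fold. The count was 353 without c30ag35 replicate 1, 247 without c30ag35 replicate 2 and 80 without c30ag77 replicate 2, and 908 with no low-count filter.

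**Figure D4:**
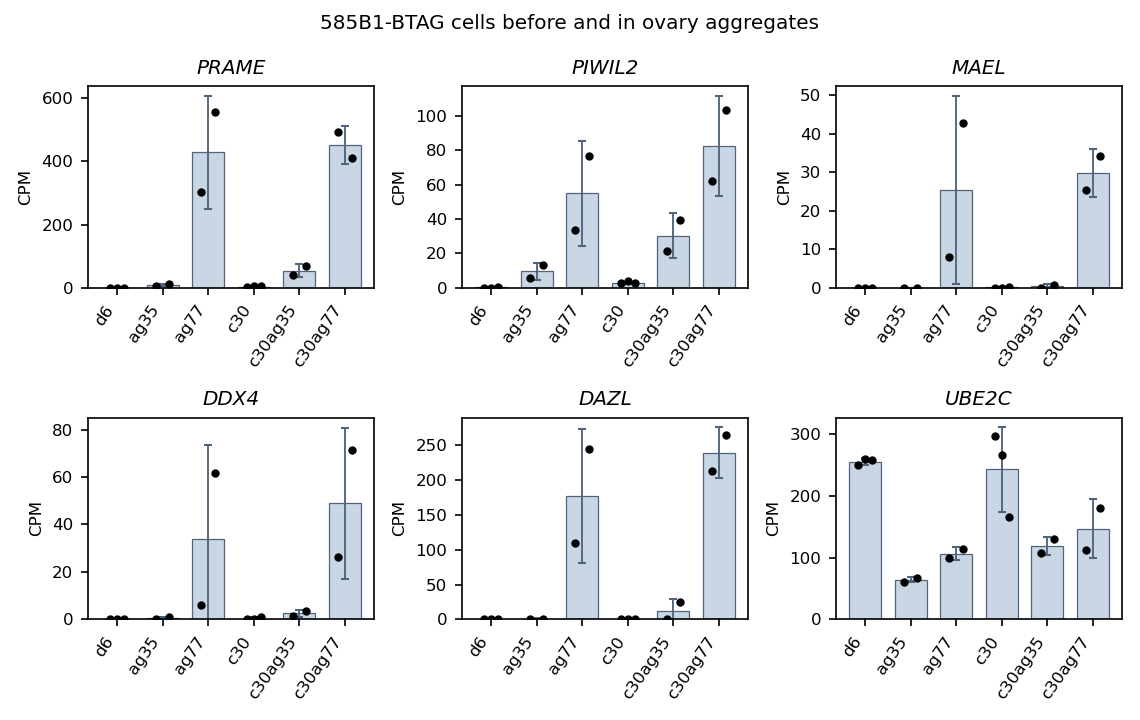
Bars show mean CPM of PRAME, PIWIL2, MAEL, DDX4, DAZL and UBE2C in d6, ag35, ag77, c30, c30ag35 and c30ag77 cells, with SD as error bars and each library as a point (n = 2 or 3). PRAME reached 429 ± 178 CPM at ag77 and 451 ± 59.2 at c30ag77.

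Whether cells that had been expanded first behaved like those that had not was asked by comparing origins at the same day (n = 2 per group). At day 35, c30-origin cells were higher in DPPA3 (1.84 ± 0.33, 227 ± 9.35 against 62.6 ± 15.4 CPM), GTSF1 (1.74 ± 0.31, 102 ± 51 against 30.2 ± 8.31 CPM) and PRAME (2.64 ± 0.37), and lower in CXCR4 (-1.69 ± 0.24), FAM20A (-3.45 ± 0.36) and ATP6V1C2 (-1.79 ± 0.24). Without ag35 replicate 1, DPPA3 (adjusted p = 0.0754), GTSF1 (0.195) and PRAME (0.0711) did not pass, nor did DPPA3 without ag35 replicate 2 (0.11) or c30ag35 replicate 2 (0.0779), or GTSF1 without c30ag35 replicate 2 (0.186) or in a fit of these groups alone (0.085). Proliferation genes were higher in 4 of 32 cases, 20 within the list (camera adjusted p = 2.23e-21; 0.127 with an estimated correlation). In all, 110 genes were called, 28 higher and 82 lower, with 100 at least 2-fold apart. The count was 16 without ag35 replicate 1, 66 without ag35 replicate 2, 29 without c30ag35 replicate 2, 35 in a fit of these groups alone and 257 with no low-count filter.

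At day 77, the origins differed in 7 genes, all lower in c30-origin cells, each with an adjusted p of 0.0445. They were VIM (-1.01 ± 0.19, 399 ± 122 against 802 ± 66.4 CPM), FN1 (-3.00 ± 0.50, 5.66 ± 5.89 against 47.6 ± 9.27 CPM), COL1A1 (-3.59 ± 0.63, 3.23 ± 2.88 against 40.7 ± 0.806 CPM), S100A16 (-1.38 ± 0.26), S100A6 (count ratio 0.0355, 0.00718 to 0.107), IGF2, down at least 19.4-fold to no counts, and IGFBP7 (-2.58 ± 0.46), which the gene rule did not name and which was added after its value was seen. Without c30ag77 replicate 1, FN1 (adjusted p = 0.0841), S100A16 (0.244), COL1A1, S100A6, IGF2 and IGFBP7 (0.251 each) and VIM (0.436) did not pass. Without c30ag77 replicate 2, S100A6 (0.0901), IGFBP7 (0.331), IGF2 (0.415) and S100A16 (0.633) did not. Without ag77 replicate 1, COL1A1 (0.0693), FN1 (0.142), VIM (0.161), S100A16 (0.265) and IGFBP7 (0.507) did not, and without ag77 replicate 2, S100A6 (0.103) and IGF2 (0.154). DAZL (0.44 ± 1.04) and DDX4 (0.52 ± 0.87) did not pass, each with an adjusted p of 1. Mesenchyme genes were lower in 4 of 22 cases, 10 within the list (camera adjusted p = 3.02e-22, and 0.00287 with an estimated correlation). The proliferation list was higher with no single gene called (camera adjusted p = 2.04e-05; 0.368 with an estimated correlation), and the amnion list lower with none called and 4 within the list (camera adjusted p = 2.34e-05; 0.151 with an estimated correlation). The count was 17 by DESeq2, 45 with no low-count filter, 0 with a stricter one and 0 in a fit of these groups alone, and 1, 3, 9 and 37 without c30ag77 replicates 1 and 2 and ag77 replicates 1 and 2.

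The change from day 35 to day 77 was called different between origins in 2 genes. It was higher in c30-origin cells for the proton pump gene ATP6V1C2 (2.01 ± 0.35, adjusted p = 0.0455) and lower for NLRP2 (-2.51 ± 0.39, adjusted p = 0.0246), whose counts are uncertain because of NLRP7. DESeq2 called 15 such genes, no low-count filter 47, a stricter one 1 and a fit of these groups alone 0. Both calls ended without ag35 replicate 1 or 2 or c30ag35 replicate 2, and that of ATP6V1C2 without c30ag77 replicate 1. Leaving out any of the 8 libraries moved the count. Across 13512 genes, which are not independent replicates, the changes of both origins correlated at r = 0.529 and Spearman's rho = 0.501. Genes called higher in both numbered 77, against 3.6 in a chance overlap, and genes called lower in both 144, against 11.6, with 0 called in opposite directions.

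Expansion was examined in the second line, 1383D6, against its own d6 cells (n = 2 per group). At c30, DPPA3 rose by 2.87 ± 0.47 (27.6 ± 4.22 against 3.68 ± 0.537 CPM), KIT by 1.69 ± 0.28 and SMARCA2 by 5.12 ± 0.30, while ID3 (-8.13 ± 0.63, 4.56 ± 0.96 against 1344 ± 139 CPM), ID2 (-5.90 ± 0.38), ID1 (-4.84 ± 0.32) and POU5F1 (-0.90 ± 0.15) fell. LEFTY1 rose by 5.48 ± 0.80 (108 ± 32.2 against 2.39 ± 0.51 CPM), the calprotectin subunit S100A9 by 7.67 ± 0.44, and HENMT1, which modifies piRNAs, by 2.74 ± 0.31. The cartilage collagen COL2A1 fell by -7.41 ± 0.53, NANOG by -0.74 ± 0.24, a call that ended on leaving out any of the 4 libraries (adjusted p up to 0.244), and the glucose transporter SLC2A3 by -3.24 ± 0.26 (49.8 ± 12.3 against 478 ± 4.08 CPM). NANOS3 (0.07 ± 0.27) and SOX17 (-1.63 ± 0.51, adjusted p = 0.0672) did not pass, but SOX17 did with no low-count filter (0.0144), a minimum count of 30 (0.0487) or these groups alone (2.61e-08).

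FAM9C (4.22 ± 0.39), FGF18 (4.27 ± 0.54), the protease ADAM8 (4.65 ± 0.52), DND1 (2.42 ± 0.40) and KHDC3L, at least 530.2-fold, rose at 1383D6 c30. PRPH (-6.40 ± 0.52), COL9A2 (-5.21 ± 0.44) and SHISA3 (-5.07 ± 0.47) fell. Glycolysis and hypoxia genes fell in 13 of 26 cases, 19 within the list (camera adjusted p = 1.13e-07; 0.415 with an estimated correlation). Naive genes rose in 5 and fell in 1 of 8, 5 and 1 within the list (camera adjusted p = 0.0173; 0.169 with an estimated correlation). In total 2108 of 12218 genes were called, 987 higher and 1121 lower, with 1244 called without d6 replicate 1, 1401 without c30 replicate 1 and 1003 without c30 replicate 2.

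At 1383D6 c10 (n = 2 per group), DPPA3 rose by 3.75 ± 0.46 (50.3 ± 0.599 against 3.68 ± 0.537 CPM), SMARCA2 by 5.39 ± 0.30, ABCG2 by 6.32 ± 0.60 and LEFTY1 by 5.73 ± 0.80 (129 ± 1.26 against 2.39 ± 0.51 CPM). ID3 fell by -6.03 ± 0.54, COL2A1 by -7.63 ± 0.52 (1.37 ± 0.467 against 270.4 ± 61.5 CPM) and the cancer-associated architectural gene HMGA2 by -4.09 ± 0.39. Naive pluripotency genes rose in 4 and fell in 1 of 8 cases, 5 and 1 within the list (camera adjusted p = 0.021; 0.343 with an estimated correlation). In all, 1672 genes were called, 855 higher and 817 lower, with 848 without d6 replicate 1 and 840 without c10 replicate 1.

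From c10 to c30 in 1383D6 (n = 2 per group), 29 genes were called, 6 higher and 23 lower. ERVW-1 rose by 2.53 ± 0.32 (123 ± 16.8 against 21.1 ± 1.53 CPM), and ACO1 (-2.32 ± 0.27), the retinoic acid binding gene CRABP1 (-2.06 ± 0.29) and FN1 (-2.35 ± 0.34) fell. Without c30 replicate 2, CRABP1 (adjusted p = 0.138) and FN1 (0.265) did not pass, nor did FN1 without c10 replicate 1 (0.108) or c30 replicate 1 (0.201). The cholesterol synthesis list fell with 1 of 23 genes, 2 within the list (camera adjusted p = 2.28e-05, and 0.038 with an estimated correlation). The gonadal germ cell list rose with no single gene called and 2 within the list (camera adjusted p = 1.83e-04, and 0.0469 with an estimated correlation). The count was 8 without c10 replicate 1, 8 without c30 replicate 1, 3 without c30 replicate 2 and 120 with no low-count filter.

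Across 11449 genes tested in both lines, the c30 to d6 changes correlated at r = 0.818 and Spearman's rho = 0.737, where genes are not independent replicates. Genes called higher in both lines numbered 733, against 146.5 in a chance overlap, genes called lower in both 871, against 178.6, and 4 were called in opposite directions.

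The lines were compared by the difference of their changes, 1383D6 minus 585B1-BTAG (n = 2 and 3 per group), d6 differences included. From d6 to c30, LEFTY2 (5.08 ± 0.73), LEFTY1 (2.45 ± 0.53), the tachykinin gene TAC3 (2.79 ± 0.27) and ADAM8 (2.55 ± 0.56) had the higher change in 1383D6, and LEFTY1 and LEFTY2 are close copies whose counts are uncertain. DPPA3 (-2.89 ± 0.59, adjusted p = 0.0164), COL2A1 (-3.42 ± 0.64), S100A6 (-3.60 ± 0.47) and the zinc finger gene HKR1 (-2.04 ± 0.35) had the lower change there. Leaving out 1 library ended the calls of LEFTY1 in 5 cases (adjusted p up to 0.173), ADAM8 in 5 (up to 0.203), DPPA3 in 3 (up to 0.136), COL2A1 in 2 (up to 0.311), LEFTY2 in 1 (0.0638, without 1383D6 d6 replicate 1) and HKR1 in 1 (0.0765, without 1383D6 c30 replicate 2). DPPA3 stood at 27.6 ± 4.22 CPM in 1383D6 c30 and at 206 ± 7.56 in 585B1-BTAG c30. The early germ cell list was lower, 1 of 21 called and 2 within the list (camera adjusted p = 0.0117; 0.136 with an estimated correlation). In all, 50 of 12680 genes were called, 32 higher and 18 lower, with 105 under no low-count filter. The count was 33 and 31 without d6 replicate 2 and c30 replicate 1 of 585B1-BTAG, and 22 and 18 without d6 replicate 1 and c30 replicate 2 of 1383D6.

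From d6 to c10, LEFTY2 (4.71 ± 0.70), LEFTY1 (2.39 ± 0.53), TAC3 (3.28 ± 0.27), the calcium-binding gene NECAB1 (2.98 ± 0.39) and IGFBPL1 (2.47 ± 0.52) had the higher change in 1383D6. COL2A1 (-4.26 ± 0.59), the transporter SLC47A1 (-2.73 ± 0.52), the neuronal filament PRPH (-2.46 ± 0.53) and SALL1 (-2.35 ± 0.46) had the lower change. Leaving out 1 library ended the calls of LEFTY1 in 6 cases (adjusted p up to 0.15), IGFBPL1 in 5 (up to 0.105), PRPH in 6 (up to 0.137), SALL1 in 3 (up to 0.0726), SLC47A1 in 2 (up to 0.184) and LEFTY2 in 1 (0.119, without 1383D6 d6 replicate 1). The count was 60 of 12680 genes, 34 higher and 26 lower, and 129 with no low-count filter. Leaving out d6 replicate 2, c10 replicate 1 and c10 replicate 3 of 585B1-BTAG gave 38, 28 and 36, and leaving out d6 replicate 1, d6 replicate 2 and c10 replicate 1 of 1383D6 gave 11, 115 and 21.

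In 1383D6 at c10, ITGA6-low cells were compared with ITGA6-high cells sorted from the same day (n = 2 per group). NANOS3 fell by -8.76 ± 0.47 (2.17 ± 2.12 against 909.5 ± 352 CPM), SOX17 by -3.94 ± 0.65 (13.1 ± 4.33 against 194 ± 10.5 CPM), TCL1A by -7.72 ± 0.44 and KIT by -3.57 ± 0.33. SOX2 rose by 6.94 ± 0.71 (174 ± 104 against 1.46 ± 0.953 CPM) and DNMT3B by 4.92 ± 0.38 (1437 ± 646 against 46.5 ± 18.6 CPM). POU5F1 did not pass (-0.04 ± 0.15, 1174 ± 35.3 against 1164 ± 13 CPM), and NANOG fell by -1.09 ± 0.25. The primed pluripotency factor OTX2 rose (count ratio 236, 41.4 to 9398), as did the retinoic acid hydroxylase gene CYP26A1 (7.01 ± 0.74), FZD7 (6.37 ± 0.56) and the Wnt-pathway repressor TCF7L1 (5.83 ± 0.46).

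GPC4 (5.93 ± 0.34), BCAT1 (5.86 ± 0.35) and the neural gene NES (3.11 ± 0.39) were higher in ITGA6-low cells. DPPA3 (-3.38 ± 0.46), KHDC3L (-7.21 ± 0.93), the naive pluripotency factor TFCP2L1 (-6.33 ± 0.52) and IL32 (-6.30 ± 0.46) were lower. Early germ cell genes were lower in 17 of 21 cases and higher in 3, 3 and 17 within the list (camera adjusted p = 7.23e-16, and 0.00206 with an estimated correlation). Without the 4 genes used in sorting, 13 of 17 were lower and 3 higher (1.31e-12, and 0.0183). Primed and shared pluripotency genes were higher in 14 and lower in 3 of 23, 15 and 3 within the list (camera adjusted p = 9.86e-10, and 0.0306 with an estimated correlation), and naive genes lower in 6 of 8, 6 within the list (camera adjusted p = 1.43e-07, and 0.0136 with an estimated correlation). In ITGA6-low cells, 20 of 26 glycolysis and hypoxia genes were higher and 1 lower, 21 and 1 within the list, SLC2A3 by 2.86 ± 0.25 (camera adjusted p = 2.86e-09; 0.282 with an estimated correlation). In total 3815 genes were called, 1841 higher and 1974 lower, with 3089 at least 2-fold apart.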

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

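Of the tests below, that of the cell line or sort gate was chosen only after its result was seen, and the ITGA6-low test before. The results in this part drew attention because a change differed between the cell lines or between the origins of aggregate cells, by a test of the difference itself.

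From d6 to c10, 60 genes changed differently. Differences, 1383D6 minus 585B1-BTAG in log2 with those at d6 included, were 4.71 for LEFTY2, 3.28 for TAC3, 2.98 for NECAB1 and 2.47 for IGFBPL1. They were -4.26 for COL2A1, -2.73 for SLC47A1, -2.46 for PRPH and -2.34 for SALL1.

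From d6 to c30, 50 genes changed differently. Differences were 5.08 for LEFTY2, 2.79 for TAC3, 2.55 for ADAM8 and 2.45 for LEFTY1. They were -3.60 for S100A6, -3.42 for COL2A1, -2.89 for DPPA3 and -2.04 for HKR1.

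Between c30 and d6 origins, 2 genes differed in the change from day 35 to day 77 of aggregate culture. Differences were 2.01 for ATP6V1C2 and -2.51 for NLRP2 (uncertain because of NLRP7), and both genes already differed at day 35.

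The d6 to c30 changes of LEFTY1 and LEFTY2 were higher in 1383D6, where both means rose, than in 585B1-BTAG, where that of LEFTY2 fell, which was weighed against ITGA6-low cells left among the sorted c30 cells. LEFTY1 stood at 96.3 CPM in ITGA6-low c10 cells and at 108 in c30, so 111.9% of the c30 cells would have to be such cells, whereas SOX2, at 174 CPM in ITGA6-low cells and with 0 counts in c30, allows 0.318%. This argues against carried-over ITGA6-low cells of the c10 kind as the source of that level. The lines already differed at d6, where LEFTY1 stood at 2.39 CPM in 1383D6 and 10.5 in 585B1-BTAG, and LEFTY2 at 2.90 and 41.2. At c30, LEFTY1 stood at 108 and 84.8, and LEFTY2 at 32.7 and 13.9. The lower LEFTY difference at c10, 2.39, decides nothing on lines or gates, as the c10 and c30 changes share the d6 libraries. Gates of expanded cells cannot have set the larger factor between the lines at d6, where no gate is given. At c30, lines and gates cannot be told apart, because each line had its own.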

How the results depend on the processing

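Runs without the chromosome 9 and 13 genes, without the shifted libraries, with crossed blocks and of lists without sort genes were chosen only after the results were seen. Counts given first are those of the report. RLE scaling left every count of called genes within 1.5-fold, and neither it nor DESeq2 moved the median change of all genes by more than 0.036 log2. DESeq2 gave 3 for 1 in c50 against c30 (33.3% higher in place of 100%), 17 for 7 in c30ag77 against ag77 and 15 for 2 in the difference between origins (66.7% higher in place of 50%). With no low-count filter, counts were 12 for 1 in c50 against c30, 1 for 0 in c70 against c50 and in c90 against c70, 2 for 0 in c120 against c90, 908 for 557 in c30ag77 against c30ag35, 257 for 110 in c30ag35 against ag35, 45 for 7 in c30ag77 against ag77, 47 for 2 in the difference between origins, 677 for 420 in iMeLC against iPSC, 120 for 29 in 1383D6 c30 against c10, 129 for 60 in the c10 to d6 difference between lines and 105 for 50 in the c30 to d6 difference. With a minimum count of 30, which tests fewer genes, they were 0 for 7 in c30ag77 against ag77 and 1 for 2 in the difference between origins, and the correlation of origins was 0.603 for 0.529. The replicate block gave 1131 for 485 in c120 against c10, 1013 for 432 in c30 against c10, 11 for 1 in c50 against c30 and 1 for 0 in c90 against c70. Where the rule for pairs was not met, although in the trend each library correlated best with its own number in 90 of 90 cases and 43 of 45 pairs exceeded 0.1, the block gave 709 for 422 in the trend, 1102 for 687 in ag77 against ag35, 1095 for 557 in c30ag77 against c30ag35, 211 for 110 in c30ag35 against ag35, 12 for 7 in c30ag77 against ag77 and 12 for 2 in the difference between origins. It moved no other count by more than 1.5-fold. Besides calls given in the report, the block called, where the rule was not met, DDX4 in ag35 against d6 (adjusted p = 0.0233), NANOG in c10 (0.0281), NANOG, ENO1 and MEST in c30 (0.0139, 7.90e-06 and 0.0159) against d6 and POU5F1 in c30ag35 against c30 (0.0133), but not FN1 in c30ag77 against ag77 (0.2). Crossed blocks gave 1778 for 1672 in 1383D6 c10 against d6 and 31 for 29 in c30 against c10. Fits of the compared groups alone, which hold fewer libraries, gave 291 for 485 in c120 against c10, 1 for 0 in c70 against c50, 414 for 687 in ag77 against ag35, 35 for 110 in c30ag35 against ag35, 0 for 7 in c30ag77 against ag77, 0 for 2 in the difference between origins and 775 for 420 in iMeLC against iPSC. Of 175 gene list calls, 34 held with an estimated correlation. Without day 120 the trend gave 96 for 422, and without the shifted libraries, which leaves fewer of them, counts were 1900 for 3383 in c120 against d6, 28 for 485 in c120 against c10 and 50 for 422 in the trend. Apart from runs with fewer libraries or genes, the cause was not tested.

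Leaving out each library in turn, where a lone library left in a group is assumed to vary like the other groups, gave 2648 to 2726 in c10 against d6, 3397 to 3445 in c30 against d6, 2828 to 2957 in c120 against d6, 217 to 691 in c120 against c10, 214 to 274 in c30 against c10, 0 to 1 in c50 against c30, 0 to 0 in c70 against c50, 0 to 0 in c90 against c70, 0 to 2 in c120 against c90 and 189 to 509 in the trend. The ranges were 3740 to 4720 in ag35 against d6, 211 to 945 in ag77 against ag35, 1153 to 2008 in c30ag35 against c30, 80 to 532 in c30ag77 against c30ag35, 16 to 145 in c30ag35 against ag35, 1 to 37 in c30ag77 against ag77, 0 to 19 in the difference between origins and 114 to 413 in iMeLC against iPSC. They were 2900 to 3741 in d6 against iMeLC, 840 to 1574 in 1383D6 c10 against d6, 1003 to 1651 in 1383D6 c30 against d6, 3 to 24 in 1383D6 c30 against c10, 2809 to 3293 in ITGA6-low against high, 11 to 115 in the c10 to d6 difference between lines and 18 to 63 in the c30 to d6 difference between lines. These fits hold fewer libraries.

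Of 329 gene results named in the report, 290 were called. Over 3903 values under the alternatives, none turned a called direction, 3721 kept their side of the threshold, 138 fell short of it and 44 newly passed. In all, 51 gene results lost their call somewhere, 36 on leaving out 1 library, 14 in fits of the compared groups alone, 12 without the shifted libraries and 8 with the minimum count of 30.

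Other splits of the libraries were also tested. For 3 libraries against 3, the splits are too few for a share under 0.05. The real split gave 3224 in c10, 3919 in c30 and 3383 in c120 against d6, 485 in c120 against c10 and 1 in c50 against c30, and the highest other split gave 0 in each, so that 1 of 10 splits gave as many. In c30 against c10 the real split gave 432 and the highest other 9, from a split that parted 1 pair of numbers, while those parting all 3 pairs gave 0. In c70 against c50 and c90 against c70 all 10 splits gave 0, and in c120 against c90 the real split gave 0 and another, parting 1 pair, gave 8. In the trend, the real days gave 422 genes and shuffled days at most 133 (1 of 100 as many). Same-number libraries are alike, so chance stays open. Depth limits what can be seen, since 3 counts equal up to 2.00 CPM and 2-fold changes were recovered in 64.2% of simulated cases for c30 against d6.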

Other observations

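Of the tests below, those of base composition, an extra chromosome 13 copy and another cell type among the sorted cells were chosen only after the result was seen. The neighbouring genes TCL1A and TCL1B parted during expansion: TCL1A stood at 583 to 701 CPM at c10, 691 to 856 at c30, 162 to 278 at c50, 29.5 to 51.4 at c70, 6.56 to 56.5 at c90 and 2.21 to 18.6 at c120, while TCL1B stood at 323 to 422 at c10 and 225 to 395 at c120. GTSF1 stood at 9.01 to 15.4 CPM in c30 and at 0 to 2.38 in c120, where its call against d6 (adjusted p = 0.022) ended without d6 replicate 1 (0.0651) or 3 (0.0614) or c120 replicate 1 (0.126). In ag77, which came from d6 cells, it stood at 136 to 184. The imprinted noncoding RNA MEG3 had 0 counts at d6 and reached 190.5 to 231 CPM at ag77 and 186 to 214 at c30ag77. Ribosomal protein genes took 23.4% of counts at d6, 31.4% at ag35, 32.7% at c30ag35, 28.6% at ag77 and 26.6% at c30ag77.

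Genes of chromosome 13 were higher in c90 replicate 2 (median 0.37, 94.2% of 103 genes above the c10 mean) and in c120 replicate 2 (0.622, 95.1%), and genes of chromosome 9 in c120 replicate 3 (0.381, 79.9% of 199), while none of 10000 random gene sets reached such medians. A base composition trend is argued against, since the higher shift of chromosomes 4 and 18, also poor in G and C, was 0.038. A few genes or one part of chromosome 13 are argued against by the genes in 4 stretches of the chromosome, the lowest of which had a median of 0.59. An extra copy of chromosome 13 in most cells of that culture may explain the shift, which at 0.622 lies near the 0.585 of log2(3/2), and an extra copy of part of chromosome 9 may explain the other, whose 4 stretches had medians of -0.013, 0.54, 0.442 and 0.428. This is a hypothesis from the data that showed it, DNA was not measured here, and a karyotype of those cultures would test it.

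Mesenchyme genes were lower in c30-origin than in d6-origin cells at day 77. Cells of another type among the sorted d6-origin cells, which passed a reporter gate, may have brought them, but of 5 mesenchyme genes tested 3 were below -1, VIM (-1.01 ± 0.19, adjusted p = 0.0445), COL1A2 (-1.96 ± 0.39, 0.148) and SPARC (-1.83 ± 0.38, 0.148), while LGALS1 (0.29 ± 0.19) and TAGLN (0.53 ± 0.46, at 6.45 CPM) showed no passing change (1 each). Somatic cells of the fetal ovary carried along may have contributed, and the median of the gonadal somatic list was -0.85, short of the -1 asked for. The somatic cells were of mouse origin, and reads were not mapped to mouse here. These explanations and a difference between the origins cannot be told apart, because each group had 2 libraries and 4 of these 5 genes did not pass.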
